A study of Mus musculus with 12 samples.

How the data were processed

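RNA bound to tagged ribosomes was pulled down from the neonatal mouse inner ear to measure hair cell transcripts. In RiboTag mice, Cre recombinase switches on an HA-tagged ribosomal protein, so that an antibody against HA pulls down ribosomes from the cells that carry Cre. Cre was expressed here from the Gfi1 locus, which in the inner ear is active in hair cells, the sensory receptors of hearing and balance. Heterozygotes (Gfi1Cre/+) kept 1 unmodified copy of Gfi1 and mutants (Gfi1Cre/Cre) carried Cre on both copies, per the labels. The dose of Cre thus differed with genotype. An effect of that dose on which cells carry the tag cannot be told apart from the loss of unmodified Gfi1. Cochlear and vestibular tissue was taken at postnatal day 0 to 1, with 3 libraries per genotype and organ and 12 libraries in all. Per the labels' protocols, cochlear libraries were made with a NuGEN ultralow-input kit and vestibular libraries with a New England Biolabs directional kit. Organ and kit therefore could not be told apart, and levels were never compared between organs. The series describes the triplicates as independent biological replicates. Input RNA without immunoprecipitation was not analysed here.

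The deposited values were CPM, read counts scaled to the total of each library, 1 table per library, per the file headers and the values. TopHat and the genome build GRCm38 were named in the submitters' processing notes, with no version; the counting tool, its strand setting and the gene annotation were not given in the sources used here. Every value was a whole multiple of the value of 1 read in its library, to within 1e-06, for 100% of values. The whole read counts could thus be recovered from the deposited CPM. The total that scaled each library held 7531518 to 9363796 reads in the cochlea and 18951026 to 29370267 in the vestibule. Of these totals, 0.184% to 0.211% in the cochlea and 0.119% to 0.729% in the vestibule lay outside the listed genes, with 0.684% and 0.729% in the 2 vestibular replicate 1 libraries. A single read was worth 0.107 to 0.133 CPM in the cochlea and 0.0340 to 0.0528 CPM in the vestibule. In the cochlea 28342 genes were listed and in the vestibule 24726, with 23427 in both, and the rule behind these lists was not given in the sources used here. Coordinates were taken from GENCODE M21 on GRCm38, which held 28300 and 24703 of the listed identifiers. Gene symbols listed more than once (17 in the cochlea, 8 in the vestibule) were kept apart by identifier.

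Genes with at least 1 CPM in at least 3 of the 6 libraries of an organ were tested, 17985 in the cochlea and 15595 in the vestibule. Mutants were compared with heterozygotes within each organ by limma 3.58.1 (trend) in R 4.3.3 on log2(CPM + 1), without a replicate block, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes at low levels. The difference between organs was an interaction term in a single fit of the 12 libraries, the cochlear change minus the vestibular change, over the 14674 genes tested in both. A constant effect of the kit on a gene cancels in that difference, but an effect of the kit on the size of a fold change does not. Shared calls were compared by a two-sided Fisher exact test with the number expected for independent lists. Gene lists were tested with camera at an inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison; lists with fewer than 5 tested members have counts alone. Figures were drawn with matplotlib 3.10.9.

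The grouping, tests, 24 gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took Gfi1, then the 12 largest rises and 12 largest falls per organ among called genes whose 3 mutant libraries all lay on one side of the 3 heterozygous libraries, leaving out predicted genes. It added the 5 largest positive and 5 largest negative differences between organs, with the mutant libraries fully on one side in at least 1 organ in the direction that set the sign, and up to 4 members per list by smallest p. Some genes that the rule takes are not reported here. The lists of biological processes were hair cell transcription factors, hair bundle and mechanotransduction, hair cell synapse, channels and calcium buffers, outer hair cell genes, inner hair cell genes, neuronal transcription factors, neuronal cytoskeleton, RNA-binding and synaptic genes, Notch pathway, cell cycle, p53 targets and apoptosis, unfolded protein and amino acid stress response, and GFI1-repressed genes known from blood cells. The lists of markers were supporting cell, macrophage, granulocyte, erythroid, Schwann and satellite glia, mesenchyme, endothelium, melanocyte, skeletal muscle, mitochondrially encoded transcripts, immediate early genes and sex-linked genes.

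Alternatives were pseudocounts of 0.25 and 4, no filter or a filter of 5 CPM, median-of-ratios rescaling, quantile normalization, robust empirical Bayes, array weights, a fold limit of 2, a single fit of the 12 libraries, leaving out each library, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads. Removal of both cochlear replicate 3 libraries, removal of both vestibular replicate 1 libraries, the edgeR fit with the block, the block for the overlap of calls between organs and a restriction to protein-coding genes were added after seeing the data.

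Replicate numbers in the labels run from 1 to 3 in every group, and whether they pair the libraries was read from the data alone. Deviations from the group means of same-numbered heterozygous and mutant libraries correlated across genes at 0.226, 0.226 and 0.420 in the cochlea and at 0.766, 0.508 and 0.599 in the vestibule. Every library correlated best with its own number, so values with the replicate number as a block stand beside results whose call they change or whose count they move by more than 1.5 times. To look for a library deposited in duplicate, counts of libraries of a group were compared; every pair differed by more than sampling noise (chi-square per degree of freedom 8.41 to 25.6 in the cochlea and 29.3 to 95.9 in the vestibule), so none was merged. Separate preparations of a single sample would differ in this way too, so the independence of the replicates rests on the series' description alone.

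The tests were tried on simulated reads with known changes, 50 genes for each size of change in each organ. In the cochlear simulation limma recovered 98% of genes with a log2 change of -2, 64% at -1, 94% at 1 and 100% at 2, and 8.25% of its calls were false (17.0% with the block). In the vestibular simulation it recovered 84%, 34%, 38% and 100%, with 10.5% of calls false (9.70% with the block). In the simulation of the difference between organs it recovered 77.6%, 10.9%, 19.6% and 92.9%, with 9% of calls false. These shares of false calls lay above the 5% that the adjusted p names. Each came from a single simulated set without replicate pairs, so how the block performs on paired libraries was not tested. Because strand use in the counting is not given, genes that overlap others are uncertain; exons shared with another gene made up 39.4% of Mab21l1, 39.0% of Chrna10, 31.8% of Hes5, 20.5% of Dll1, 18.1% of Uchl1, 17.1% of Lypd1, 14.1% of Ina, 13.0% of Neurod1 and 10.3% of Pitx1. Members of families with near-identical copies, such as Hba-a1 and Hba-a2, Hspa1a and Hspa1b, Tpsb2 and Tpsab1, the clustered protocadherins and Strc, are likewise uncertain.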

Results

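Ribosome-bound RNA was pulled down with a tag that Gfi1Cre switches on, used to reach hair cells, from the cochlea, the organ of hearing, and the vestibule, the organ of balance, of newborn mice. Each organ had 3 libraries from heterozygotes carrying a single Gfi1Cre allele and 3 from mutants with Cre on both copies of Gfi1, a gene for a zinc finger transcriptional repressor needed by hair cells and by granulocytes. The pull-down also held transcripts known from other cells. In heterozygotes macrophage markers summed to 2941 to 3640 CPM in the cochlea and 8534 to 11133 CPM in the vestibule, and mesenchyme markers to 2928 to 4048 and 5157 to 5425 CPM, beside 4824 to 5483 and 7769 to 8530 CPM for hair bundle genes. Library totals ranged from 7531518 to 9363796 reads in the cochlea and from 18951026 to 29370267 in the vestibule, so that 1 read corresponded to 0.107 to 0.133 CPM and 0.0340 to 0.0528 CPM. Means are given with the SD over 3 libraries, and fold changes are mutant minus heterozygote on the log2(CPM + 1) scale with limma's standard error. The first principal component separated the genotypes in the cochlea (40.6% of variance), with heterozygotes at -31.5 to -21.9 and mutants at 24.5 to 28.8. In the vestibule the first component (45.5%) separated both replicate 1 libraries, at -29.2 and -51.7, from the other 4 at 4.96 to 36.0, and the second (34.9%) separated the genotypes. Heterozygotes lay at -42.6 to -14.6 on that second component and mutants at 13.8 to 32.9. Sex-linked genes, as a check of the mix of pups, did not pass the list test in the cochlea (camera, Benjamini-Hochberg adjusted p = 0.123) or in the vestibule (0.928). Without cochlear heterozygote replicate 3 that cochlear value was 5.15e-05, and without both replicate 3 libraries 0.000120, towards higher levels in mutants. The list joins Xist, expressed in females, with genes of the Y chromosome. A changed mix of sexes moves these in opposite directions, so the test could miss it. In the cochlea 4 members had a positive log2 fold change and 1 a negative one, with a median of 0.42 and 2 called higher with the replicate block. In the vestibule 2 were positive and 3 negative, with a median of -0.08 and none called with the block. A different mix of sexes between the cochlear genotypes therefore cannot be excluded.

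Gfi1 itself (chromosome 5, 107716657 to 107726036 on GRCm38, minus strand) fell in both organs. In the cochlea its level went from 133 ± 30.1 CPM in heterozygotes to 69.5 ± 5.43 CPM in mutants, a log2 fold change of -0.90 (SE 0.16) (limma, Benjamini-Hochberg adjusted p = 0.00355). In the vestibule it went from 489 ± 42.2 CPM in heterozygotes to 214 ± 19.8 CPM in mutants, a log2 fold change of -1.19 (SE 0.13) (limma, Benjamini-Hochberg adjusted p = 0.00234). All 3 mutant libraries lay below all 3 heterozygous libraries in each organ. Reads were still assigned to Gfi1 in every mutant library, and which exons the Cre allele replaces is not given in the sources used here.

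**Figure D1:**
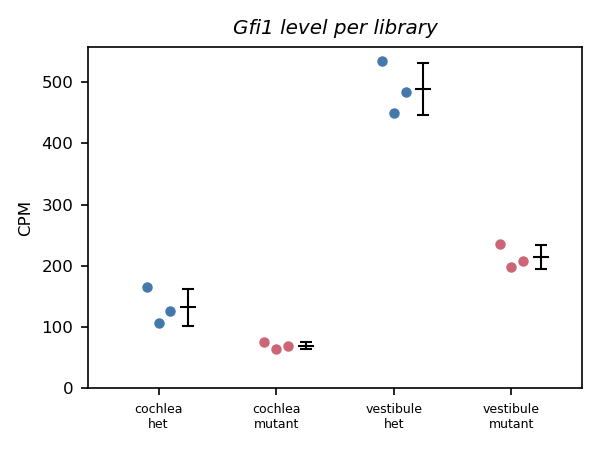
Gfi1 level in CPM (vertical axis) in each library, by organ and genotype; dots are libraries and the bar beside them is the mean with its SD (n = 3). Mutant libraries averaged 69.5 CPM in the cochlea and 214 CPM in the vestibule, below the heterozygous means of 133 and 489 CPM.

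The cochlear comparison asked which ribosome-bound transcripts differed when both copies of Gfi1 carried Cre. The largest rises included neuronal and sensory neuron transcription factors that were close to undetected in heterozygotes. Lhx2, a LIM homeodomain factor (chromosome 2, 38339281 to 38369733), rose from 0.290 ± 0.413 CPM in heterozygotes to 88.6 ± 50.4 CPM in mutants, a log2 fold change of 6.03 (SE 0.34). St18, a zinc finger factor of the Myt1 family (chromosome 1, 6487231 to 6860940), rose from 0.931 ± 0.719 CPM in heterozygotes to 119 ± 33.2 CPM in mutants, by 5.99 (SE 0.28). Neurod1, a neuronal bHLH factor (chromosome 2, 79452521 to 79456751), rose from 0.850 ± 0.851 CPM in heterozygotes to 115 ± 56.0 CPM in mutants, by 5.98 (SE 0.35). Gfy, a Golgi protein of olfactory sensory neurons, rose by 5.97 (SE 0.34), and Casr, the calcium-sensing receptor, by 4.25 (SE 0.44). Further rises were found for the synaptic vesicle protein gene Synpr (4.04, SE 0.21), the kinase anchor gene Sphkap (3.49, SE 0.27), the homeobox gene Pitx1 (3.39, SE 0.26), the transporter gene Slc10a4 (3.25, SE 0.30), the POU factor gene Pou3f1 (3.20, SE 0.31), the photoreceptor cadherin gene Cdhr1 (3.16, SE 0.38) and the vesicular glutamate transporter gene Slc17a6 (3.14, SE 0.26). The highest limma Benjamini-Hochberg adjusted p among these 12 genes was 0.000184, for Cdhr1.

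The largest falls in the mutant cochlea included genes of hair cells. Erich5 (chromosome 15, 34453305 to 34473892) fell, with a log2 fold change of -3.87 (SE 0.25). Slc26a5, which encodes prestin, the motor protein of outer hair cells (chromosome 5, 21810655 to 21865604), went from 18.1 ± 5.44 CPM in heterozygotes to 0.890 ± 0.698 CPM in mutants and changed by -3.38 (SE 0.32). Kcna10, a potassium channel gene, changed by -3.30 (SE 0.24), Kncn, which encodes kinocilin of hair cells, by -3.49 (SE 0.22), and Strc, which encodes stereocilin of the hair bundle, by -2.84 (SE 0.29). Elfn1, a synaptic adhesion gene, changed by -3.55 (SE 0.22), the protein kinase gene Pkn3 by -3.22 (SE 0.22) and the granulocyte gene S100a9 by -2.95 (SE 0.36). R3hdml (-3.11), Chst13 (-3.04), Toporsl (-2.99) and Ofcc1 (-2.92) completed the 12, with a highest limma Benjamini-Hochberg adjusted p of 0.000195, for S100a9. Of 17985 genes tested, 341 were higher and 453 lower in mutants, 455 of these 794 by at least 2-fold. The groups did not overlap for 17.5% of tested genes, against 10% by chance for libraries without pairs or other structure. In the other splits of the 6 libraries the share was 4.59% to 6.71% where all 3 same-numbered pairs were parted and up to 17.7% where 1 was. With the replicate number as a block 1532 genes were called (757 higher, 775 lower), including all 794, and without both replicate 3 libraries, whose mitochondrially encoded transcripts summed to 6736 and 6982 CPM against 22602 to 31593 CPM in the others, 708 were called.

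**Figure D2:**
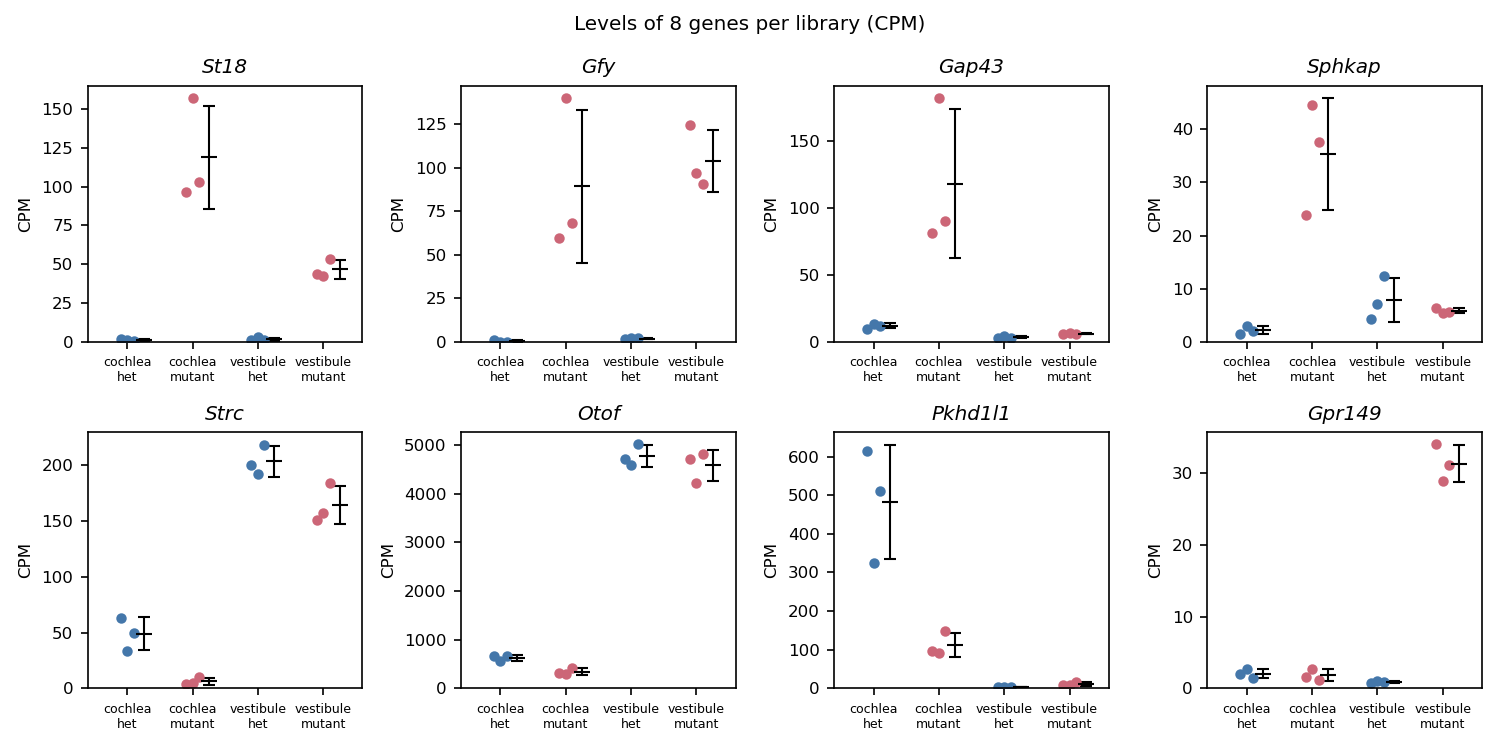
Levels in CPM (vertical axes) of 8 genes in each library, by organ and genotype; dots are libraries and the bar beside them is the mean with its SD (n = 3). St18 and Gfy rose in mutants of both organs, Gap43 and Sphkap rose in the cochlea, Strc and Otof fell in the cochlea, Pkhd1l1 fell in the cochlea, and Gpr149 rose in the vestibule.

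Hair bundle and mechanotransduction genes fell together in the mutant cochlea. Of 34 tested members 19 fell and none rose (27 fell when adjusted over the list alone), with a median log2 fold change of -0.78. The list passed with camera (Benjamini-Hochberg adjusted p = 6.94e-34), but not with an estimated correlation (adjusted p = 0.0674 with an estimated correlation). Myo3a, an unconventional myosin of stereocilia tips, fell from 227 ± 35.3 CPM in heterozygotes to 81.9 ± 6.26 CPM in mutants (log2 fold change -1.45, SE 0.14). Cdh23, the tip link cadherin, changed by -1.77 (SE 0.19) and Myo3b by -1.40 (SE 0.15). Genes of the hair cell synapse, channels and calcium buffers fell as well, 9 of 14 (11 over the list alone), median -0.87, including the nicotinic receptor subunit genes Chrna9 (-2.03, SE 0.18) and Chrna10 (-1.63, SE 0.17), the latter uncertain because 39.0% of its exon bases are shared with another gene, and the Ras-related Rasd2 (-0.86, SE 0.13). Its camera Benjamini-Hochberg adjusted p was 3.91e-19, and adjusted p = 0.0674 with an estimated correlation. Among outer hair cell genes 4 of 9 fell and 2 rose (5 and 2 over the list alone; camera adjusted p = 0.00204; adjusted p = 0.127 with an estimated correlation). Strip2 (-2.55, SE 0.27) and Slc26a5 were among those that fell. The factor Bcl11b also fell (-1.44, SE 0.29), a call lost without heterozygote replicate 1 or 2 or mutant replicate 1 (adjusted p up to 0.0559). Neurod6 (1.46, SE 0.31) and Insm1 rose, calls lost without heterozygote replicate 1 (adjusted p up to 0.0753) and without heterozygote replicate 1, 2 or 3 or mutant replicate 1 or 2 (adjusted p up to 0.172). Among inner hair cell genes 3 of 8 fell, also over the list alone, namely the vesicular glutamate transporter gene Slc17a8 (-0.99, SE 0.16), Slc7a14 (-1.03, SE 0.17) and the otoferlin gene Otof (-0.89, SE 0.15), which acts in exocytosis. That list had a camera Benjamini-Hochberg adjusted p = 0.00459, adjusted p = 0.349 with an estimated correlation, and 0.0880 without mutant replicate 2.

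Transcription factors of hair cells did not pass as a list in the cochlea. The list of hair cell transcription factors had a median of -0.00 over 10 genes (camera, Benjamini-Hochberg adjusted p = 0.983). Its mean was 0.08, opposite in sign to the median. Atoh1, which starts hair cell differentiation, stood at 51.0 ± 13.9 CPM in heterozygotes and 69.3 ± 3.96 CPM in mutants (0.47, SE 0.18; limma, Benjamini-Hochberg adjusted p = 0.254). The only member called was the outer hair cell and neuronal factor Insm1 (1.06, SE 0.27; limma, Benjamini-Hochberg adjusted p = 0.0428), with Barhl1 (-0.66, SE 0.18) also called lower over the list alone. With the block 2 higher and 1 lower were called. The Insm1 call was lost without heterozygote replicate 1, 2 or 3 or mutant replicate 1 or 2 (adjusted p up to 0.172).

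Neuronal genes rose in the mutant cochlea in both lists. Among neuronal transcription factors 9 of 17 rose and none fell (10 over the list alone), median 1.04, with Nhlh2 (3.12, SE 0.34) and Prrxl1 (2.54, SE 0.26) beside St18 and Neurod1. The camera Benjamini-Hochberg adjusted p was 4.10e-13, and adjusted p = 0.139 with an estimated correlation. Among 30 genes of the neuronal cytoskeleton, RNA binding and synapse 13 rose and 1 fell (14 and 1 over the list alone), median 0.49. For this list camera gave a Benjamini-Hochberg adjusted p = 3.77e-11, and adjusted p = 0.270 with an estimated correlation. Gap43, a growth cone protein gene, rose from 11.9 ± 1.89 CPM in heterozygotes to 118 ± 55.7 CPM in mutants (3.13, SE 0.25). The neuronal tubulin gene Tubb3 rose by 3.03 (SE 0.36), Stmn4 by 2.76 (SE 0.33) and the intermediate filament gene Ina by 1.48 (SE 0.20). Syt1, a calcium sensor of synaptic vesicles, was the member that fell (-0.64, SE 0.16; limma, Benjamini-Hochberg adjusted p = 0.0373), a call lost without heterozygote replicate 1 or 2 or mutant replicate 2 or 3 (adjusted p up to 0.193). Schwann and satellite glia markers, which accompany ganglion neurons, had a median of -0.08 with none of 12 called.

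Granulocyte markers summed to 32.1 to 58.3 CPM in heterozygotes and 4.13 to 9.12 CPM in mutants, and 5 of 6 fell (6 over the list alone), such as Ngp (-2.62, SE 0.28) and the lactoferrin gene Ltf (-2.16, SE 0.28). Camera gave a Benjamini-Hochberg adjusted p = 4.10e-13, and adjusted p = 0.0674 with an estimated correlation. Macrophage markers rose, median 0.24, with 2 of 19 higher, also over the list alone, the lysozyme gene Lyz2 (0.69, SE 0.13) and the Fc receptor gene Fcgr3 (0.71, SE 0.17), whose call was lost without heterozygote replicate 1 or mutant replicate 1, 2 or 3 (adjusted p up to 0.154). Their values were camera adjusted p = 0.00644, adjusted p = 0.430 with an estimated correlation, and 0.0560 without heterozygote replicate 3. Notch pathway genes fell as a list (2 of 16 lower, 5 over the list alone; camera adjusted p = 0.0207; adjusted p = 0.349 with an estimated correlation), with the ligand genes Dll3 (-1.83, SE 0.25) and Dll4 (-1.09, SE 0.23), the latter call being lost without heterozygote replicate 2 or mutant replicate 2 (adjusted p up to 0.0699); with the block 5 were lower. Its camera value was 0.134 without heterozygote replicate 3 and 0.0683 without both replicate 3 libraries. Hrk, an activator of apoptosis, rose by 2.72 (SE 0.20) as the only called member of the p53 and apoptosis list, which did not pass (camera adjusted p = 0.204). Id2, a target of GFI1 repression in blood cells, rose by 1.49 (SE 0.13), while its list, with 2 members higher over the list alone and with the block, did not pass (0.101; 0.0444 without heterozygote replicate 2 and 0.0242 without mutant replicate 3). The immediate early genes Dusp1 (1.97, SE 0.25) and Jun (1.18, SE 0.19) rose, and their list had a camera adjusted p = 0.0767, reaching 0.0242 without mutant replicate 3, 0.0417 without heterozygote replicate 1 and 0.0473 without heterozygote replicate 2.

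The other cochlear lists did not pass with camera. Supporting cell markers had S100a1 lower (-0.75, SE 0.14) and a Benjamini-Hochberg adjusted p of 0.768. The values were 0.873 for cell cycle genes, 0.883 for erythroid genes, 0.788 for glia, 0.873 for mesenchyme and 0.873 for endothelium, with no member called. In the supporting cell, erythroid and endothelium lists the median was above 0 and the test below it, with mean log2 changes of -0.01, -0.05 and 0.02; in the cell cycle and mesenchyme lists the mean was above 0 and median and test below. Unfolded protein response genes had a camera adjusted p of 0.107, and 0.0340 without mutant replicate 1, towards lower levels. Mitochondrially encoded transcripts had a median of -0.20 and an adjusted p of 0.252, or 0.00163 with the block, 1.21e-05 without heterozygote replicate 3 and 0.0191 without mutant replicate 2. Without both replicate 3 libraries that value was 0.00153. With the block 2 members each were lower in the unfolded protein, supporting cell and mitochondrial lists and 2 higher among sex-linked genes; over the list alone 1 unfolded protein response gene was lower. None of 3 melanocyte and 2 skeletal muscle genes with enough expression was called.

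**Figure D3:**
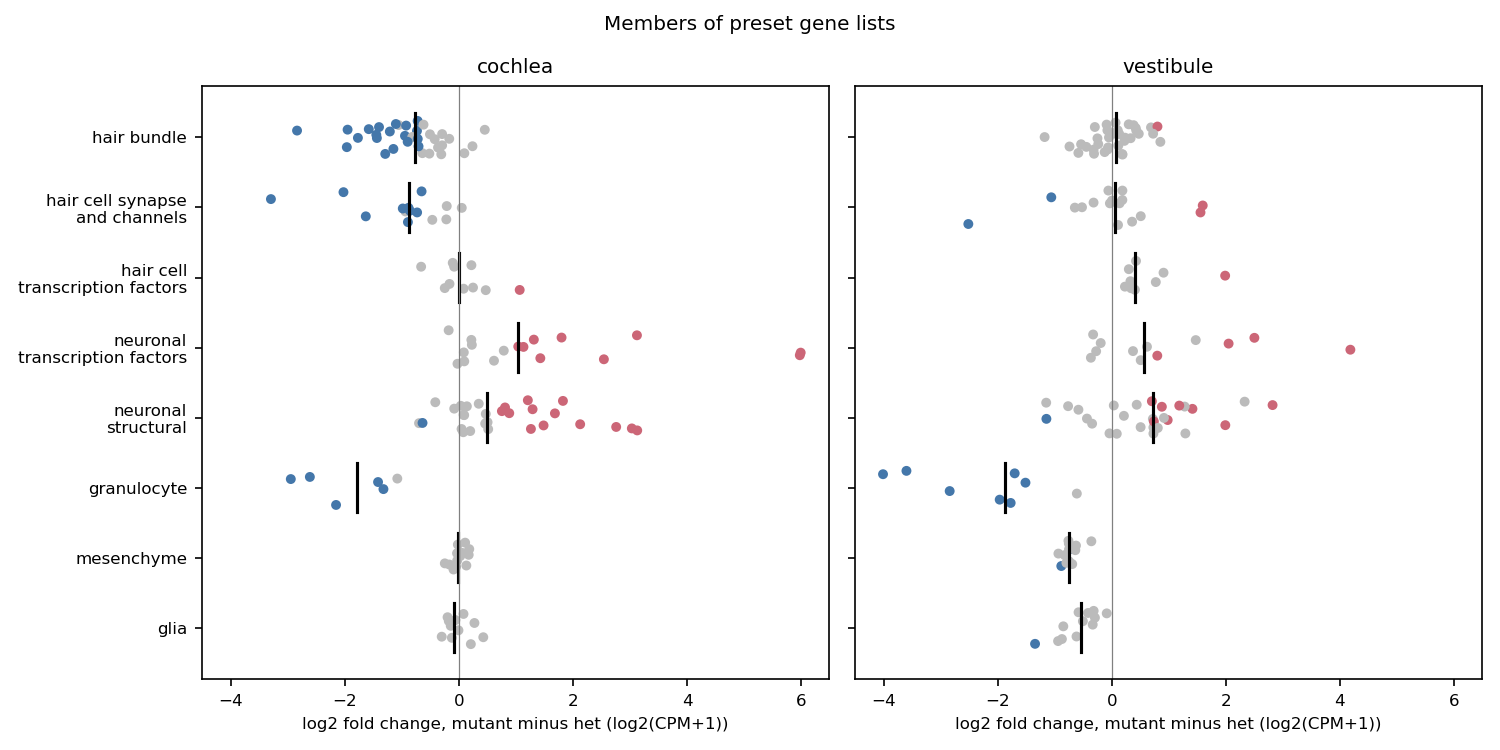
Log2 fold change, mutant minus heterozygote on log2(CPM + 1) (horizontal axis), of each tested member of 8 gene lists in cochlea and vestibule; coloured dots passed an adjusted p of 0.05 (red higher, blue lower), grey dots did not, and the black bar is the list's median. Hair bundle genes had a median of -0.78 in the cochlea and 0.07 in the vestibule, and granulocyte markers -1.79 and -1.87.

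The vestibular comparison asked the same question in the balance organs. Dgkk, a diacylglycerol kinase gene (chromosome X, 6779306 to 6948363), rose from 1.68 ± 1.53 CPM in heterozygotes to 97.4 ± 16.3 CPM in mutants, a log2 fold change of 5.33 (SE 0.36). Gfy (chromosome 7, 45176349 to 45179569) rose by 5.18 (SE 0.19), the water channel gene Aqp6 (chromosome 15, 99601400 to 99605477) by 4.89 (SE 0.21), the phospholipase gene Pla2g2d by 4.50 (SE 0.24), Nap1l5 by 4.21 (SE 0.29) and St18 by 4.18 (SE 0.28). The orphan receptor gene Gpr149 rose by 4.10 (SE 0.19), Mab21l1, uncertain because 39.4% of its exon bases are shared with another gene, by 4.05 (SE 0.25), Tdo2, which encodes tryptophan dioxygenase, by 3.74 (SE 0.21), and Ddc, which encodes dopa decarboxylase, by 3.57 (SE 0.15). The sodium channel gene Scn9a (3.55) and Lix1 (3.27) completed the 12 largest rises, with a highest limma Benjamini-Hochberg adjusted p of 0.000810, for Scn9a.

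Falls in the mutant vestibule were led by a calcium pump and by genes of granulocytes and mast cells. Atp2a3, a calcium pump of the endoplasmic reticulum (chromosome 11, 72961169 to 72993044), fell from 460.0 ± 26.5 CPM in heterozygotes to 21.3 ± 2.43 CPM in mutants, a log2 fold change of -4.38 (SE 0.13). The granulocyte genes Ltf (-4.01, SE 0.28), Ngp (-3.60, SE 0.28) and S100a9 (-2.84, SE 0.18) fell, as did the mast cell protease genes Mcpt4 (-3.30, SE 0.41) and Cma1 (-2.88, SE 0.35). Cpa3 (-2.65, SE 0.44) and Mrgprb1 (-2.61, SE 0.45), also of mast cells, fell too, but the Cpa3 call was lost without heterozygote replicate 2 or 3 (adjusted p up to 0.0798) and the Mrgprb1 call without heterozygote replicate 2 or 3 (adjusted p up to 0.0912). The muscle-type glycolytic gene Pgam2 (-3.04), the immunoglobulin gene Ighm (-2.68), Gpr141b (-2.61) and the matricellular gene Nov (-2.60) completed the 12, with a highest limma Benjamini-Hochberg adjusted p of 0.0178, for Mrgprb1. Of 15595 genes tested 376 were higher and 170 lower, 351 of these 546 by at least 2-fold. The groups did not overlap for 22.3% of genes, against 10% by chance, 2.52% to 3.19% in the other splits that part all 3 pairs and up to 19.4% in those that part 1. With the replicate block 3634 genes were called (1637 higher, 1997 lower), all 546 among them. Without both replicate 1 libraries the count was 863 (532 higher, 331 lower), and it was 226 without heterozygote replicate 2, 293 without heterozygote replicate 3, 254 without mutant replicate 2 and 253 without mutant replicate 3.

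Hair bundle genes of the vestibule did not pass as a list. The median over 35 genes was 0.07 (camera, Benjamini-Hochberg adjusted p = 0.407). Only Clrn1, the Usher syndrome gene for clarin, passed (0.80, SE 0.16; limma, Benjamini-Hochberg adjusted p = 0.0311), a call lost without heterozygote replicate 2 or mutant replicate 1, 2 or 3 (adjusted p up to 0.139). Over the list alone 2 members were higher and 3 lower, and with the replicate block 10 were higher and 8 lower. Among synapse, channel and calcium buffer genes the calcium buffer gene Ocm fell from 202 ± 8.99 CPM in heterozygotes to 34.5 ± 1.31 CPM in mutants (-2.52, SE 0.11), while Rasd2 (1.59, SE 0.12) and the parvalbumin gene Pvalb (1.56, SE 0.13) rose. Kcna10 fell (-1.06, SE 0.17; limma, Benjamini-Hochberg adjusted p = 0.0121), a call lost without heterozygote replicate 2 or 3 or mutant replicate 2 or 3 (adjusted p up to 0.0689). That list had 2 of 16 higher and 2 lower (2 and 4 over the list alone, 3 and 5 with the block), a camera Benjamini-Hochberg adjusted p = 0.854, and a mean of -0.03, opposite in sign to its median of 0.06. Outer hair cell genes had 2 of 8 higher and 2 lower, also over the list alone, and 2 higher and 4 lower with the block (camera adjusted p = 0.408): Ocm, Lbh (-0.75, SE 0.16), Neurod6 (1.54, SE 0.28) and Lmod3 (1.56, SE 0.23). The Lbh call was lost without heterozygote replicate 1, 2 or 3 or mutant replicate 1, 2 or 3 (adjusted p up to 0.162), that of Neurod6 without heterozygote replicate 1 or 3 or mutant replicate 1, 2 or 3 (adjusted p up to 0.109) and that of Lmod3 without mutant replicate 3 (adjusted p up to 0.0513). Among inner hair cell genes Brip1 (0.92, SE 0.16) and Slc7a14 (0.70, SE 0.11) were higher, calls lost without heterozygote replicate 2 or mutant replicate 2 or 3 (adjusted p up to 0.0933) and without heterozygote replicate 2 or 3 or mutant replicate 2 or 3 (adjusted p up to 0.0841). That list had 3 of 8 higher and 1 lower over the list alone and 4 and 1 with the block (camera adjusted p = 0.0574, and 0.0318 with the block).

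Hair cell transcription factors rose as a list in the mutant vestibule. The camera Benjamini-Hochberg adjusted p was 0.000118, and adjusted p = 0.209 with an estimated correlation. Atoh1 rose from 26.1 ± 7.55 CPM in heterozygotes to 106 ± 30.2 CPM in mutants (1.99, SE 0.27; limma, Benjamini-Hochberg adjusted p = 0.00635) and was the only 1 of 9 called, also over the list alone; with the block 6 were higher. All 9 members had a positive log2 fold change, median 0.41, among them Lhx3 (0.91, SE 0.30), which alone did not pass (limma, Benjamini-Hochberg adjusted p = 0.182). In the same libraries the median log2 fold change was -0.75 for mesenchyme markers, -0.54 for glia and -0.54 for endothelium, and mitochondrially encoded transcripts summed to 2678 to 8481 CPM in heterozygotes and 1244 to 5083 CPM in mutants.

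Neuronal genes rose in the vestibule as well. Among neuronal transcription factors 4 of 12 rose (6 over the list alone), median 0.56, including Pou4f2, a factor of retinal ganglion cells (2.50, SE 0.28), beside St18; camera adjusted p = 3.07e-05, adjusted p = 0.193 with an estimated correlation. The others were Prrxl1 (2.05, SE 0.32) and Nhlh1 (0.80, SE 0.13), calls lost without heterozygote replicate 3 (adjusted p up to 0.0527) and without heterozygote replicate 2 or 3 or mutant replicate 2 (adjusted p up to 0.0777). With the block 7 members were higher and 1 lower. Of 28 genes of the neuronal cytoskeleton, RNA binding and synapse 8 rose and 1 fell (14 and 5 over the list alone; 16 and 5 with the block), median 0.72. The camera Benjamini-Hochberg adjusted p was 5.27e-07, and adjusted p = 0.0867 with an estimated correlation. Elavl4, a neuronal RNA-binding protein gene, rose from 3.85 ± 0.637 CPM in heterozygotes to 33.1 ± 3.16 CPM in mutants (2.82, SE 0.19), Uchl1 by 1.99 (SE 0.17) with 18.1% of its exon bases shared with an antisense gene and so uncertain, and Snap25, of the synaptic fusion machinery, by 1.18 (SE 0.15). Syt1 was the member that fell (-1.15, SE 0.17; limma, Benjamini-Hochberg adjusted p = 0.0102), a call lost without heterozygote replicate 2 or mutant replicate 2 (adjusted p up to 0.0673). Glia markers, which accompany ganglion neurons, had a median of -0.54 and mesenchyme markers of -0.75.

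Markers of several other cell types were lower in the mutant vestibule. Granulocyte markers summed to 84.5 to 125 CPM in heterozygotes and 12.1 to 12.9 CPM in mutants, and 7 of 8 fell, also over the list alone (camera adjusted p = 3.65e-11; adjusted p = 0.0867 with an estimated correlation). Mesenchyme markers summed to 5157 to 5425 against 3073 to 3121 CPM; 2 of 13 fell (8 over the list alone, 12 with the block), median -0.75, namely the collagen genes Col3a1 (-0.89, SE 0.11) and Col1a1 (-0.73, SE 0.14), the latter call being lost without heterozygote replicate 2 or 3 or mutant replicate 1, 2 or 3 (adjusted p up to 0.122). Their camera Benjamini-Hochberg adjusted p was 3.95e-07, and adjusted p = 0.159 with an estimated correlation. Glia markers summed to 406 to 465 against 258 to 288 CPM, with 1 of 12 lower. The count was 5 over the list alone and 7 with the block, with a camera adjusted p = 9.53e-05, and adjusted p = 0.0867 with an estimated correlation. Endothelial markers summed to 91.3 to 141 against 59.0 to 90.9 CPM with none of 9 called (5 lower with the block; camera adjusted p = 0.00645; adjusted p = 0.429 with an estimated correlation; 0.0730 without mutant replicate 1). Cell cycle genes fell as a list, median -0.39, with none of 16 called (3 lower over the list alone, 8 with the block; camera adjusted p = 8.81e-05; adjusted p = 0.193 with an estimated correlation). Melanocyte markers had none of 5 called (2 lower over the list alone), a camera adjusted p = 0.0451, adjusted p = 0.429 with an estimated correlation, and 0.110 with the block. That call was lost without heterozygote replicate 1 (0.0710) or 2 (0.0805), without mutant replicate 1 (0.0946) or 3 (0.129), and without both replicate 1 libraries (0.128). Mitochondrially encoded transcripts summed to 2678 to 8481 CPM in heterozygotes and 1244 to 5083 CPM in mutants, with none of 7 called (7 lower with the block; camera adjusted p = 0.00645; adjusted p = 0.573 with an estimated correlation). Without heterozygote replicate 2 the value was 0.0585, without mutant replicate 3 it was 0.0798, and without both replicate 1 libraries 0.123.

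The other vestibular lists did not pass with camera. Hrk rose by 1.51 (SE 0.18) in the p53 and apoptosis list (Benjamini-Hochberg adjusted p = 0.407), with the cell cycle inhibitor gene Cdkn1a (0.73, SE 0.12). Cdkn1a was also the only called member of the GFI1-repressed list (0.702), and its call was lost without heterozygote replicate 2 or 3 or mutant replicate 2 or 3 (adjusted p up to 0.0877). Heyl, a Notch effector, fell (-0.87, SE 0.12), and the Notch ligand gene Jag2 rose (0.89, SE 0.14), a call lost without heterozygote replicate 2 or mutant replicate 2 or 3 (adjusted p up to 0.0826). The Notch list had an adjusted p of 0.390, with 6 members higher and 1 lower over the list alone and 7 and 4 with the block. Values were 0.407 for the unfolded protein response, 0.290 for supporting cells, 0.133 for macrophages, 0.928 for erythroid genes and 0.407 for immediate early genes. Supporting cell markers reached 0.0233 without heterozygote replicate 1, and macrophage markers 0.00383 without heterozygote replicate 3 and 0.0349 without mutant replicate 2, both towards lower levels. Median and test differed in sign for the Notch, p53 and erythroid lists, and the mean differed from both in the GFI1-repressed list (-0.03). None of 3 skeletal muscle genes was called (1 higher over the list alone and with the block), and their mean of 0.01 differed in sign from their median. In the p53 list 2 were higher and 1 lower over the list alone. With the block members were called as follows: p53 3 higher and 1 lower, unfolded protein response 1 higher and 3 lower, GFI1-repressed 2 higher and 2 lower, supporting cell 2 higher and 5 lower, macrophage 0 higher and 4 lower and immediate early 2 higher and 4 lower. With an estimated correlation 0 of the 9 list calls in the cochlea and 0 of the 10 in the vestibule held. A call lost there need not mean correlated members. For cochlear outer hair cell genes the estimated correlation was -0.07, yet the unadjusted camera p went from 0.000557 to 0.0230. For vestibular glia it was -0.03, and that p went from 2.49e-05 to 0.0113. How often this setting can pass with 3 libraries per group was not tested. The fry test asks whether a list's genes move one way and sets them against no other genes. It called 8 and 10 lists, not all of them those of camera. In the cochlea the neuronal cytoskeleton, RNA-binding and synaptic genes (fry, Benjamini-Hochberg adjusted p = 0.0572), inner hair cell genes (0.238), Notch pathway (0.125) and macrophage markers (0.143) did not pass, while p53 (0.00841), GFI1-repressed (0.00764) and immediate early genes (0.00405) did. In the vestibule endothelium (0.108), melanocyte (0.0588) and mitochondrially encoded transcripts (0.314) did not pass with fry, and outer hair cell (0.0365), inner hair cell (0.00687) and p53 genes (0.0428) did.

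Changes in the organs overlapped beyond what independent lists give. Among 14674 genes tested in both, 122 were higher in both organs against 7.46 expected from lists of 310 and 353 (two-sided Fisher exact test, p = 9.66e-121). St18, Gfy, Casr, Synpr, Slc17a6, Dgkk, Pla2g2d and Hrk were among them. Another 43 were lower in both against 4.18 expected from lists of 432 and 142 (two-sided Fisher exact test, p = 6.26e-32), among them Gfi1, R3hdml, S100a9, Pgam2 and Atp2a3. With the replicate block 346 genes were higher in both organs, 4.62 times the number expected (two-sided Fisher exact test, p = 4.45e-157), and 183 lower in both, 1.93 times the number expected (p = 1.91e-19). Without the block these ratios were 16.4 and 10.3. Genes are not independent replicates, so these p-values do not measure how far the overlap would recur in other animals. Across genes, the log2 fold changes had a Pearson r of 0.30 and a Spearman rho of 0.14.

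**Figure D4:**
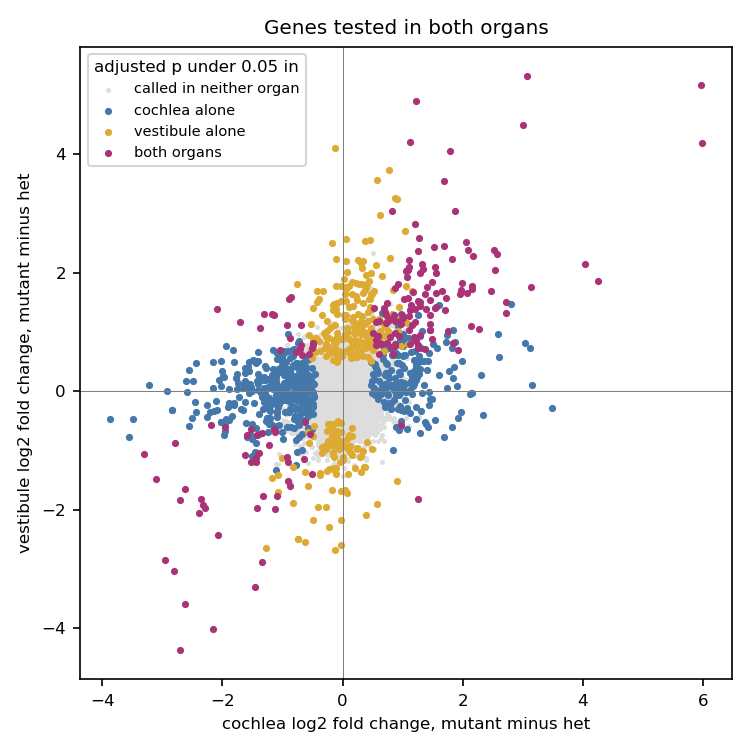
Log2 fold change, mutant minus heterozygote, in the cochlea (horizontal axis) and the vestibule (vertical axis) for the 14674 genes tested in both; colours mark genes called in neither organ, the cochlea alone, the vestibule alone or both. Genes called in both lie mostly in the upper right (122) and lower left (43), with 20 lower in the cochlea and higher in the vestibule.

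The difference of the genotype effects between organs was tested directly. Sphkap rose in the cochlea (3.49) and had a log2 fold change of -0.28 in the vestibule, a difference of 3.77 (SE 0.45). Lypd1, a modulator of nicotinic receptors with 17.1% of its exon bases shared with another gene and so uncertain, had a difference of 3.08 (SE 0.34), Cdhr1 of 3.05 (SE 0.66) and Nov of 2.57 (SE 0.39). Gpr149 rose in the vestibule (4.10) against -0.13 in the cochlea, a difference of -4.23 (SE 0.34). Pkhd1l1, a coat protein gene of stereocilia (chromosome 15, 44457494 to 44601369), fell in the cochlea (-2.09) from 483 CPM and rose in the vestibule (1.39) from 3.30 CPM, a difference of -3.48 (SE 0.40). Its vestibular call was lost without heterozygote replicate 1, 2 or 3 or mutant replicate 2 or 3 (adjusted p up to 0.188). Differences were -3.40 (SE 0.48) for Erich5, -3.31 (SE 0.30) for Pkn3 and -3.68 (SE 0.33) for Aqp6, and the highest limma Benjamini-Hochberg adjusted p of these 9 genes was 0.0188, for Cdhr1. Aqp6 was at 0.0847 CPM in cochlear heterozygotes, and its difference did not pass with edgeR (Benjamini-Hochberg adjusted p = 0.664) or DESeq2 (0.579). In all 461 genes differed, 104 with a more positive and 357 with a more negative change in the cochlea, and 22 were called in opposite directions, such as Rasd2 and Pvalb; Fisher's exact test gave p = 0.00574 for 20 genes lower in the cochlea and higher in the vestibule (10.4 expected) and p = 0.772 for 2 the other way. With the block 1955 differed (1012 and 943), and without vestibular heterozygote replicate 2 the count was 302.

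Gene lists also differed between organs. Hair bundle genes were lower in the cochlea relative to the vestibule, with medians of -0.78 and 0.09 over the 34 members tested in both (camera, Benjamini-Hochberg adjusted p = 4.44e-24), and so were synapse, channel and calcium buffer genes, with medians of -0.87 and 0.12 (2.76e-18). For both the adjusted p = 0.00705 with an estimated correlation, and 0.135 with an estimated correlation and the block. Mesenchyme markers, whose medians were -0.02 and -0.75, differed the other way (1.57e-05; adjusted p = 0.109 with an estimated correlation). Neuronal transcription factors (0.217) and neuronal cytoskeleton, RNA-binding and synaptic genes (0.880) did not pass the camera test of the difference.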

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

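The tests of swaps within pairs, strand, cell mixture, ganglion carry-over, scaling, hair cell share and outer hair cell loss were chosen only after the results were seen; the other splits of the libraries were planned. The difference of the genotype effects between organs, tested by limma's interaction term, drew attention to the genes and lists of the 2 paragraphs that follow; the vestibular replicate 1 libraries were noticed on the principal components, and the neuronal and hair bundle genes in the cochlear comparison.

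In all 461 genes had a genotype effect that differed between organs. Among 100 drawn assignments of genotype within each organ, of 200 possible, only 1, the real one, gave as many, and the highest other gave 253 and kept the genotype split in 1 organ. The 80 draws that kept the genotype split in neither organ all gave 0 genes. Every other draw broke up the genotype effect itself in at least 1 organ, so the draws cannot tell whether the effects differ. The draws also took no account of the pairing. Of all 32 assignments that part the 6 same-numbered pairs 2 gave as many, a share of 0.0625, so chance cannot be excluded within pairs. The other one, with 1017 genes, kept the genotype split in both organs but swapped the genotypes in 1, which turns the difference into a sum, and the highest of the remaining assignments gave 153. With the block the real assignment gave 1955, and the swapped one 2643. The cochlear change minus the vestibular change was 3.05 for Cdhr1, 3.77 for Sphkap, 3.08 for Lypd1 and 2.57 for Nov on the log2 scale. It was -3.31 for Pkn3, -3.48 for Pkhd1l1, -3.68 for Aqp6, -4.23 for Gpr149 and -3.40 for Erich5. Aqp6 rose in both organs, from 0.0847 CPM in cochlear heterozygotes. Its difference did not pass with edgeR (Benjamini-Hochberg adjusted p = 0.664) or DESeq2 (0.579). The vestibular call of Pkhd1l1 was lost without heterozygote replicate 1, 2 or 3 or mutant replicate 2 or 3 (limma, adjusted p up to 0.188).

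As lists, camera found lower changes in the cochlea than in the vestibule for hair cell transcription factors (Benjamini-Hochberg adjusted p = 0.000216), hair bundle genes (4.44e-24), synapse, channel and calcium buffer genes (2.76e-18), outer hair cell genes (0.00381), inner hair cell genes (0.000448) and Notch pathway genes (0.00788). It found higher changes in the cochlea for cell cycle (0.00692), macrophage (0.00169), granulocyte (0.0322), glia (0.00181), mesenchyme (1.57e-05), endothelium (0.0394) and immediate early genes (0.00131). With an estimated correlation only the hair bundle and the synapse lists passed (adjusted p = 0.00705 each with an estimated correlation). Neither passed once the block was added to that setting (adjusted p = 0.135 each with an estimated correlation). With the block and the inter-gene correlation of 0.01 the granulocyte value was 0.120. Mitochondrially encoded transcripts then passed at 2.03e-05, against 0.222 without the block.

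The 10 splits of the 6 libraries of an organ, of which 1 is the real one, are too few for a share under 0.05. In the cochlea the real split called 794 genes with limma and the highest other 0, against 2185 and 2034 at an unadjusted p under 0.05. In the vestibule the real split called 546 and the highest other 0, against 2511 and 2274 unadjusted. The other splits that part all 3 same-numbered pairs reached 333 unadjusted calls in the cochlea and 64 in the vestibule, and 0 with the block, against 1532 and 3634 for the real splits; the splits with the highest unadjusted counts part 1 pair.

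Both vestibular replicate 1 libraries stood apart from the other 4 on the first principal component. Of 128 genes at least 8-fold higher in these libraries than in the others on the log2(CPM + 1) scale, 101 (78.9%) had at least 50% of their exon bases inside a gene on the opposite strand, against 1767 of 16411 other genes (10.8%; two-sided Fisher exact test, p = 3.40e-71), and 0 genes were 8-fold lower. Tmem150b, for example, was at 56.6 and 58.7 CPM in these libraries and at 0.817 to 1.66 CPM in the others. Another mixture of cells is argued against as the main source of these 128 genes, since only 21.1% of them had no such neighbour. Differences of mixture too small to reach the 8-fold limit were not tested and stay open. A loss of strand information in these libraries, made with a directional kit, is a candidate explanation; it is seen in a library of each genotype, and whether counting or library preparation differed stays open.

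In the mutant cochlea 22 neuronal genes were called higher, with a median log2 fold change of 1.58. A rise of glia markers by as much as the neuronal genes is argued against. By the bounds described above, 10 of 12 Schwann and satellite glia markers had an upper 95% bound below 0.61 (highest bound 0.948). The value 0.61 is the median of all 47 tested neuronal genes. Glia markers already summed to 240 to 332 CPM in cochlear heterozygotes, so glia carried over could raise them by less. Carry-over of ganglion tissue with its glia is therefore not excluded. Scaling by the library total is argued against as the whole cause, since the median was 1.54 after median-of-ratios rescaling and 21 of 22 were still called; Nhlh1 lost its call as its change went from 1.13 (SE 0.26) to 1.08 (SE 0.29) and its limma Benjamini-Hochberg adjusted p from 0.0250 to 0.0631. Carry-over of ganglion neurons alone stays open: 16 of 30 members of the neuronal cytoskeleton, RNA-binding and synaptic list had a lower 95% bound above 0 and only Syt1 an upper bound below 0, but 4 transcripts of ganglion neurons, too few and too low to exclude it, went the other way with a median of -0.56 (3 of 4 negative, 1 called lower over the list alone). The genotype may also raise neuronal transcripts within hair cells, which stays open as untested. A change in which cells carry the tag stays open too, since mutants carry Cre on both copies of Gfi1 and heterozygotes on a single copy.

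Hair bundle genes were lower in the mutant cochlea, with a median of -0.78 over 34 genes and a range of -2.84 to 0.45, and for 19 of them the 95% interval excluded that median. Of 10 hair cell transcription factor genes 9 had a lower 95% bound above -0.78, and their median was -0.00. A fall of these 9 factors by about the bundle median is argued against. The pull-down also held transcripts of other cells, and whether those cells express the factors was not tested. The values therefore do not decide whether hair cell transcripts fell as a whole. A lower share of hair cells in the mutant samples cannot be excluded either, because the genotype may also change these genes within cells. Insm1, for example, was called higher, and Barhl1 was lower over the list alone. Loss of outer hair cells cannot be told apart from a fall within cells: outer hair cell genes had a mean of -0.77 (9 genes) and inner hair cell genes of -0.32 (8 genes), a difference of -0.45 (exact permutation test over list members, two-sided, p = 0.468). What keeps it open is the small number of genes and the spread within the outer list, in which Insm1 and Neurod6 rose. An effect of the genotype on hair bundle transcripts within hair cells may account for the pattern and stays open as untested. A change with the dose of Cre in which cells carry the tag stays open as well.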

How the results depend on the processing

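Removing replicate pairs, edgeR with the block, the block for the overlap of calls between organs and a restriction to protein-coding genes were chosen after seeing the data; the other alternatives were planned. Unless a cause is named, the cause of a change was not tested.

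In the cochlea 794 genes were called, 1532 with the replicate block, 1397 by edgeR with the block, 1242 with the block and without both replicate 3 libraries, and 455 when a 2-fold change was also required, a stricter rule by construction. Leaving out each library gave 546 to 801. In the vestibule 546 were called, 3634 with the block, 3340 by edgeR with the block, 3205 with the block and without both replicate 1 libraries, and 863 without these libraries and without the block. Array weights gave 2327, DESeq2 1234, one fit of the 12 libraries 848, no filter 358 and the 2-fold rule 351; leaving out each library gave 226 to 522. All 794 and all 546 genes were kept with the block. With the block the calls split into 757 higher and 775 lower with limma and 549 and 848 with edgeR in the cochlea, and into 1637 and 1997 with limma and 1822 and 1518 with edgeR in the vestibule. Genes whose effect differed between organs numbered 461, 1955 with the block, 1034 with array weights and 815 with DESeq2, and 302 to 453 when a library was left out. Genes higher in both organs went from 122 to 346 with the block, and genes lower in both from 43 to 183 with the block, to 71 at an adjusted p under 0.1 (10.4 expected for independent lists) and to 71 without the doubtful pairs (7.72 expected). With an estimated correlation 0 list calls held in the cochlea (9 by default, 9 to 11 when a library was left out) and 0 in the vestibule (10, and 8 to 11). That setting was not tried on the simulated reads, and its p also rose for some lists with an estimated correlation below 0.

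Of 264 list values under alternatives in the cochlea 232 kept their side of the threshold, 17 lost and 15 gained a call; in the vestibule it was 246, 23 and 7 of 276. Named genes kept theirs in 1018 of 1062 values in the cochlea (22 lost, 22 gained) and in 956 of 1080 in the vestibule (66 and 58), and 0 values reversed. Apart from the values given with results, the block changed no call of a list and took no call from a named gene, adding 12 in the cochlea and 49 in the vestibule. At 0.107 to 0.133 CPM per read in the cochlea, changes of genes near 1 CPM rested on about 10 reads or fewer per library.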

Other observations

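The lists in this part, and their tests, were all chosen after the values were seen. Motile cilia and protocadherins were picked from 8 families looked at by gene name, and their camera values are adjusted over the 7 of these with enough genes in the cochlea and the 6 in the vestibule; the lowest value of the others was 0.271 in the cochlea (potassium channels) and 0.289 in the vestibule (immunoglobulin genes).

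Several genes of motile cilia and flagella, taken by gene name, were lower in the mutant cochlea. Of 49 tested 14 fell and none rose (19 and 1 over the list alone), median -0.35, among them Cfap206 (-2.46), Cfap65 (-1.81), the radial spoke gene Rsph1 (-1.31) and the dynein gene Dnah11 (-1.26). Cfap206 was seen before the family was looked at. The list passed camera (adjusted p = 0.0130 with an estimated correlation), and passed without these 4 genes (adjusted p = 0.0166 with an estimated correlation). It did not pass without them and with the wider set of names first looked at (adjusted p = 0.0514 with an estimated correlation), or with the block (adjusted p = 0.0727 with all 49 and 0.104 without the 4, with an estimated correlation), so a fall as a group stays open. In the vestibule 1 of 55, Rsph4a, was higher (0.81), with none called over the list alone and 14 higher and 9 lower with the block (adjusted p = 0.691 with an estimated correlation). Clustered protocadherins, cell adhesion genes of neurons whose near-identical exons leave single members uncertain, had 15 of 55 higher in the mutant vestibule (23 over the list alone, 27 with the block; adjusted p = 0.0358 with an estimated correlation, 0.178 with the block). Pcdha11 (2.97 for the called one of 2 identifiers with that symbol) and Pcdhac2 (2.44) were among them, and without these genes the list did not pass (adjusted p = 0.0518 with an estimated correlation). In the cochlea 3 of 50 were higher (6 with the block; adjusted p = 0.107 with an estimated correlation).

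Gfy and Rtp1, with Lhx2 and Cdhr1, are known from olfactory sensory neurons. Of 12 olfactory genes tested in the cochlea 3 were called higher, Lhx2, Gfy and Cdhr1, the smallest of these rises being 3.16. Rtp1 was not among those tested there. The other 9 tested in the cochlea had upper 95% bounds of at most 1.29, by the normal quantile, and none was called. A rise of these 9 by as much is thus argued against. The limit of 3.16 came from genes picked for their large rises. A smaller rise of a wider olfactory programme therefore stays open. In the vestibule 3 of these 4 genes were tested and 2 were called higher, while Cdhr1 had a log2 fold change of 0.11. Of 8 other olfactory genes tested there none was called higher and 1 lower (2 higher and 1 lower with the block), with a median of -0.14. Of 4 transcripts of ganglion neurons none was called in the cochlea by limma (1 lower over the list alone; 3 of 4 had a negative log2 fold change), and 1 of 2 tested was lower in the vestibule. Mast cell genes were lower in the mutant vestibule, 6 of 10 tested (10 over the list alone and with the block; adjusted p = 0.105 with an estimated correlation). Beside the 4 genes already named as largest falls 2 of 6 others were called, with a median of -0.96 over the 6, so mast cell transcripts may be lower as a group. In the cochlea 2 of 7, Cma1 and Mcpt4, were lower (adjusted p = 0.204 with an estimated correlation), and among B cell genes 1 of 6 in the vestibule, Ighm (3 with the block), and none of 3 in the cochlea.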
